A study of Mus musculus with 24 samples.

How the data were processed

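RNA sequencing of 24 libraries was analysed: LSK and GMP cells sorted from mouse bone marrow, from 4 genotypes with 3 libraries each. Per the submitters' processing notes, reads were aligned to mm10 with STAR and expression was computed with Cufflinks; the versions are not given in the sources used here. The values deposited by the authors are FPKM, 1 per gene symbol and library, for 23991 symbols. The protocol text names SMART-Seq v4 and Nextera XT for the libraries and the series text a stranded TruSeq kit, and which was used was not settled here.

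The unit was checked on the low values. If values come from counts, low values of a gene in 2 libraries stand in ratios of small whole numbers once a depth factor is applied. Under 0.3 FPKM, with whole numbers up to 6 and a tolerance of 0.005, 39.1% to 48.2% of genes did so against WT LSK replicate 1, and 1.77% to 3.08% with a shifted factor. The factor is each library's relative depth, from 0.919 to 1.28. Correlations between replicates ran from 0.933 to 0.967. Sex was read from Xist and Y-linked genes.

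Comparisons, tests, gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a moderated test and a mean-variance trend. The 12 libraries of a population were fitted together, and all 24 for GMP against LSK in WT and for the difference of the ITD effect between populations. Genes with at least 1 FPKM in at least 3 libraries of the fit were tested, and p was adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. No other scaling was applied, since FPKM is already scaled by depth and length. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

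Gene lists numbered 33, written from general knowledge: branches of the unfolded protein response, signalling targets, mature and immature blood cell types, cell cycle, metabolism, ribosomes, and checks of the libraries. Of 1007 entries, 981 matched a symbol in the files, 6 of these by another name of the gene. Lists with at least 5 tested members were tested against all other genes with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. For length, the text gives only part of the lists with a camera adjusted p under 0.05, and this choice was made after the results were seen.

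Named genes followed a rule. Ern1, Xbp1, Flt3 and Kit were always given in the 6 comparisons of ITD with WT, IRE1_KO with WT and IRE1_KO_ITD with ITD, and 8 further ER stress genes in the Ern1 comparisons. Up to 8 genes with the highest and 8 with the lowest log2 fold change were added (5 each in the other comparisons), with adjusted p under 0.05, an absolute log2 fold change of at least 1, no overlap between the groups and a mean of at least 5 FPKM in the higher group. Up to 4 called members with the smallest p came from each list with a camera adjusted p under 0.05 or at least 3 called members. Where fewer than 5 genes passed, the 5 with the smallest p were given.

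Alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, a median-ratio size factor, the replicate number as a block, a fit of only the libraries compared, and leaving out each replicate. Chosen after the data were seen were sex as a covariate, a loess correction for GC content and length (known for 11757 of 12348 tested genes, 95.2%), leaving out the 1ng libraries, and leaving out short loci. Correlations of same-numbered libraries between groups, after removal of group means, ran from -0.372 to 0.135, so the numbers were not taken as pairs.

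Known changes were simulated to test the procedure. For ITD against WT in LSK, 76% of genes changed by 1 log2 unit and 96% of those changed by 2 were recovered; in GMP the shares were 79% and 96%, and for the difference of effects 62% and 89%. From 4 to 12 unchanged genes were called in a run. A list moved by 0.5 was called each time, but lists of correlated genes were not tested. A GC trend put into 1 group gave 2723 calls, and 0 after the correction. No library was left out and no reads were used.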

Results

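RNA was sequenced from 24 libraries of sorted mouse bone marrow cells on a C57BL/6 background. LSK cells lack lineage markers and carry Sca1 and cKit, a gate that holds stem and multipotent progenitor cells. GMP cells are granulocyte-macrophage progenitors. Each population came from 4 genotypes with 3 libraries each: wild type (WT), an internal tandem duplication of the receptor gene Flt3 (ITD), floxed Ern1 with Vav-Cre (labelled IRE1_KO), and both together (labelled IRE1_KO_ITD). Ern1 encodes IRE1α, a sensor of endoplasmic reticulum (ER) stress that splices the mRNA of the transcription factor Xbp1. The labels number the libraries of a group but do not say that each came from a separate animal, so some may be technical repeats. By Xist and Y-linked genes, all 3 ITD libraries of each population were female, against 1 female and 2 male in WT, 2 female and 1 male in IRE1_KO, and 1 female and 2 male in IRE1_KO_ITD.

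Values were FPKM (fragments per kilobase of transcript, scaled by mapped fragments) for 23991 gene symbols. FPKM summed to between 510361 and 673177 per library. From 11119 to 11471 genes reached 1 FPKM in an LSK library, and from 10436 to 10831 in a GMP library. Read totals are not given in the sources used here, but ratios of low values put each library's depth at 0.919 to 1.28 times that of WT LSK replicate 1. The column headers of the 3 IRE1_KO LSK libraries carry a 1ng tag that no other library has, and the short locus Mir6236 took 0.175% to 0.904% of their FPKM, against 4.41% to 6.24% in the other LSK libraries. Below, ± after an FPKM is the SD and ± after a log2 fold change the SE of the limma fit, each with n = 3 libraries per group. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene "rose" or "fell" where its limma adjusted p lay under 0.05.

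Ern1, the targeted gene (chromosome 11, 106394650 to 106487852, mm10), was higher rather than lower in the libraries labelled IRE1_KO. In GMP it stood at 9.06 ± 1.41 FPKM in WT and 20.6 ± 3.48 in IRE1_KO, and at 13.9 ± 2.08 in ITD and 29.4 ± 3.38 in IRE1_KO_ITD. In LSK it stood at 4.34 ± 0.539, 7.62 ± 1.04, 6.28 ± 2.21 and 11.8 ± 1.01 FPKM in the same order. A value per gene does not show which exons were read, so it checks neither the deletion nor the labels, and the genotypes below are those of the labels. Of all genes, 3 separated the 12 libraries with the Ern1 label from the 12 others without overlap: Sva and Scamp1 lay above and Tmem39a below. Sva stood at 3.76 to 9.51 FPKM in the 12 labelled libraries and at no more than 0.0699 in the others. These 3 genes were chosen after their values were seen.

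**Figure D1:**
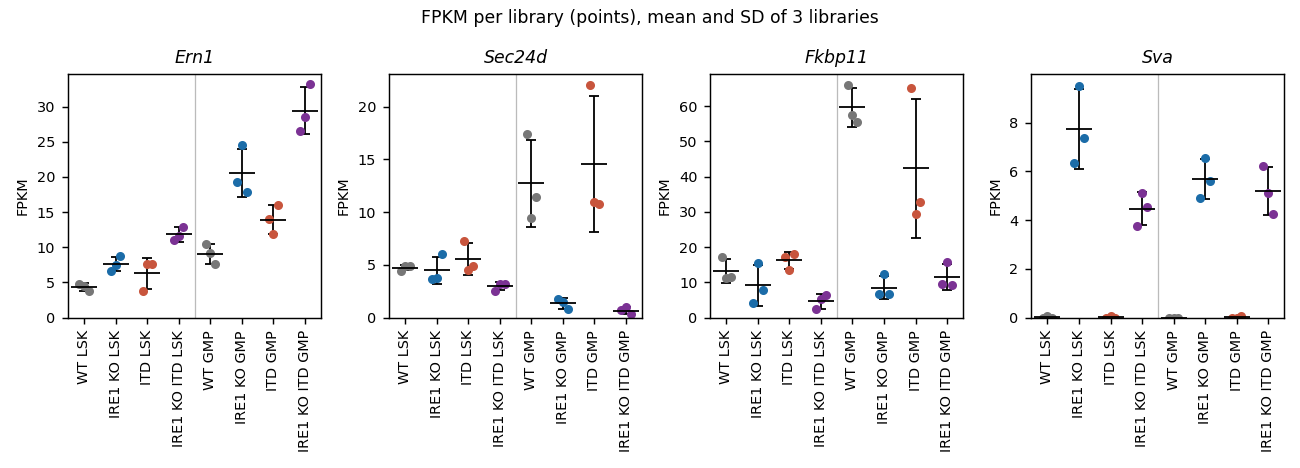
FPKM of Ern1, Sec24d, Fkbp11 and Sva in each library (points), by genotype, for LSK on the left and GMP on the right of each panel; the black line is the mean and the bar the SD of 3 libraries. In GMP, Ern1 and Sva were higher and Sec24d and Fkbp11 lower in libraries labelled IRE1_KO or IRE1_KO_ITD; Fkbp11 was 59.6 ± 5.57 FPKM in WT and 8.51 ± 3.26 in IRE1_KO.

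WT GMP were set against WT LSK to describe the 2 populations before any mutation. Myeloid genes stood far higher in GMP: Elane (neutrophil elastase) by 5.22 ± 0.49 log2 units, Ms4a3 by 5.26 ± 0.46, Prg2 (eosinophil major basic protein) by 6.13 ± 1.41 and Cst7 (cystatin F) by 2.48 ± 0.18, with limma adjusted p = 0.00130 or lower. Of the primary granule and GMP genes, 23 of 25 tested members rose (23 adjusted over the list alone) (camera adjusted p = 5.15e-18, 0.0412 with an estimated correlation). Hk3, outside the top genes, rose by 3.14 ± 0.17. Of the haematopoietic stem cell genes, 32 of 35 tested members fell (32 adjusted over the list alone) (camera adjusted p = 1.32e-15, 0.0139 with an estimated correlation), and the endothelial and stem cell receptor Robo4 fell by 3.09 ± 0.12. Gm5111 (-5.46 ± 0.27), Ctla2a (-5.33 ± 0.49) and Gimap6 (-5.07 ± 0.23) were also lower in GMP, with limma adjusted p = 5.16e-08 or lower.

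Of the XBP1 and ERAD secretory genes (the translocation, folding and degradation machinery of the ER), 51 of 63 tested members rose and 2 fell (52 and 2 adjusted over the list alone) (camera adjusted p = 4.51e-23, 0.0402 with an estimated correlation). P4hb (a protein disulfide isomerase) rose by 1.77 ± 0.09 and Dnajc3 (an ER co-chaperone) by 1.97 ± 0.11. Of the ER chaperones that ATF6 controls, 17 of 19 tested members rose (18 adjusted over the list alone) (camera adjusted p = 6.35e-14, 0.0412 with an estimated correlation). Interferon response genes lay lower, where 1 of 45 tested members rose and 34 fell (1 and 34 adjusted over the list alone) (camera adjusted p = 5.40e-07, 0.494 with an estimated correlation). Gbp2 stood at -2.38 ± 0.21 and Psmb9 at -0.66 ± 0.07. Oxidative phosphorylation genes rose in part, where 39 of 64 tested members rose and 2 fell (41 and 2 adjusted over the list alone) (camera adjusted p = 3.53e-09, 0.485 with an estimated correlation). Cycs stood at 1.23 ± 0.13 and Cox5a at 0.81 ± 0.11, and quantile normalization ended the call of the list (camera adjusted p = 0.0861). Of the monocyte, macrophage and dendritic genes, 19 of 35 tested members rose and 2 fell (19 and 2 adjusted over the list alone) (camera adjusted p = 3.48e-05, 0.494 with an estimated correlation). Fcer1g stood at 2.24 ± 0.20 and F13a1 at 4.63 ± 0.42. Limma called 6212 of 12348 genes, 2341 higher and 3871 lower in GMP. With quantile normalization, which moved the median of all genes by 0.13 log2 units, the split was 3171 and 3034. The short loci Mir7678, Mir196b, Snord61 and Mir7087 also passed, the last not without any 1 of the 6 WT libraries (adjusted p from 0.0509 to 0.0746), and Snord61 was listed at 0 in the WT LSK and Mir7087 in the WT GMP libraries.

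ITD LSK were compared with WT LSK, which asks what the Flt3 duplication does in stem and multipotent progenitor cells. Socs2, a suppressor of cytokine signalling that STAT5 induces, was at 15.6 ± 2.72 FPKM in WT and 255 ± 35.7 in ITD (log2 fold change 3.95 ± 0.16, limma adjusted p = 7.66e-07). Nov, which encodes the matricellular protein CCN3, went from 0.768 ± 0.0772 to 64.0 ± 6.32 FPKM (5.20 ± 0.26, limma adjusted p = 3.77e-06). The MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1 rose by 3.90 ± 0.64, 3.74 ± 0.62 and 3.44 ± 0.59 log2 units (limma adjusted p = 0.00350 or lower), though ITD replicate 1 stood at 85.3 FPKM of H2-Aa against a group mean of 439 ± 316. Flt3 itself fell from 149.6 ± 9.45 to 55.7 ± 2.79 FPKM (-1.41 ± 0.09, limma adjusted p = 1.29e-05). Xbp1 rose by 0.94 ± 0.19 (limma adjusted p = 0.00735), whereas the differences of Ern1 (0.40 ± 0.21, limma adjusted p = 0.194) and Kit (-0.30 ± 0.16, limma adjusted p = 0.204) did not pass.

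Of the B cell genes in ITD LSK, 16 of 18 tested members fell (17 adjusted over the list alone) (camera adjusted p = 2.35e-15, 0.178 with an estimated correlation). Cd79a of the B cell receptor fell (-3.35 ± 0.50), Ms4a1 (CD20) (-2.38 ± 0.22) and Faim3 (-2.02 ± 0.19), and the immunoglobulin joining chain Igj and the plasma cell protein Mzb1 (-3.25 ± 0.37 and -3.17 ± 0.49). Of the erythroid genes, 1 of 22 tested members rose and 15 fell (1 and 18 adjusted over the list alone) (camera adjusted p = 6.12e-12, 0.0416 with an estimated correlation). Car1 (carbonic anhydrase 1) fell (-4.15 ± 0.60), Rhd (-2.67 ± 0.29) and the transcription factor Gata1 (-2.22 ± 0.28). Late neutrophil genes fell too, where 17 of 24 tested members fell (19 adjusted over the list alone) (camera adjusted p = 6.12e-12, 0.200 with an estimated correlation). Retnlg stood at -3.49 ± 0.53 and Mmp9 at -2.22 ± 0.31. Wfdc18 stood at -2.98 ± 0.39. Monocyte, macrophage and dendritic genes went the other way, where 12 of 33 tested members rose (14 adjusted over the list alone, where 1 fell) (camera adjusted p = 0.0183, 0.605 with an estimated correlation). That call was lost without WT replicate 3 (camera adjusted p = 0.0731), ITD replicate 3 (0.0667) or ITD replicate 2 (0.105).

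Among progenitor programmes, 3 of 35 tested members rose and 19 fell (4 and 20 adjusted over the list alone) of the stem cell list (camera adjusted p = 9.49e-09, 0.160 with an estimated correlation). Ndn (necdin) fell (-2.69 ± 0.24) and Apoe (-2.05 ± 0.24), while Ifitm1 rose by 2.43 ± 0.12 and Mycn by 1.5 ± 0.15. Of the lymphoid priming genes, 14 of 21 tested members fell (14 adjusted over the list alone) (camera adjusted p = 2.07e-09, 0.160 with an estimated correlation), led by Flt3 and Il12a (-1.45 ± 0.20). Of the MAPK output genes, 4 of 19 tested members fell (5 adjusted over the list alone) (camera adjusted p = 2.93e-05, 0.222 with an estimated correlation). They included Spry2 (-1.67 ± 0.23) and Dusp6 (-2.32 ± 0.38). Of the STAT5 targets, 8 of 22 tested members rose and 4 fell (8 and 5 adjusted over the list alone). They included Cish (2.33 ± 0.33), without a call for the list (camera adjusted p = 0.669). Separately, Id2 rose by 1.74 ± 0.26.

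Of the ribosome biogenesis genes, 32 of 35 tested members rose (32 adjusted over the list alone) (camera adjusted p = 2.35e-15, 0.160 with an estimated correlation). They included Nolc1 (0.89 ± 0.09) and Ncl (0.80 ± 0.09). Of the cholesterol synthesis genes, 15 of 25 tested members rose (17 adjusted over the list alone) (camera adjusted p = 2.97e-07, 0.205 with an estimated correlation). Mvd stood at 1.52 ± 0.19 and Sqle at 1.39 ± 0.21. S phase genes rose in part, where 18 of 40 tested members rose (25 adjusted over the list alone) (camera adjusted p = 9.06e-07, 0.205 with an estimated correlation). Cdca7 stood at 0.74 ± 0.11 and Rrm1, a subunit of ribonucleotide reductase, at 0.57 ± 0.09. Among XBP1 and ERAD secretory genes, 29 of 63 tested members rose (32 adjusted over the list alone, where 2 fell) (camera adjusted p = 2.92e-06, 0.205 with an estimated correlation). They included P4hb (0.56 ± 0.07) and Pdia5 (1.49 ± 0.20). Among ER chaperones, 10 of 19 tested members rose (13 adjusted over the list alone) (camera adjusted p = 2.79e-05, 0.205 with an estimated correlation). Hsp90b1 of that list rose by 0.82 ± 0.11.

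Limma called 2650 of 11955 genes in ITD against WT LSK, 1781 higher and 869 lower. With a median-ratio size factor, which moved the median of all genes by -0.11, the split was 1106 and 1309, and with quantile normalization 1251 and 1116. The count fell to 1282 without WT replicate 2, 1550 without ITD replicate 3 and 1636 without ITD replicate 2, to 1689 in a fit of the 6 libraries alone and to 1384 with sex as a covariate. The short loci Mir704 (77 bp, 4.61 ± 1.25), Mir6386 (104 bp), Mir697 (109 bp), Mir324 (89 bp) and Mirlet7b (85 bp) passed as well. Mir6386 and Mir697 were listed at 0 in all WT and Mir324 and Mirlet7b in all ITD libraries, and all but Mir324 lost their calls without WT replicate 1, ITD replicate 2 or ITD replicate 3, Mir704, Mir6386 and Mir697 also without WT replicate 3, Mir6386, Mir697 and Mirlet7b without WT replicate 2, and Mirlet7b without ITD replicate 1 (adjusted p from 0.0502 to 0.104 for Mirlet7b, 0.0587 to 0.0777 for Mir704, 0.0541 to 0.0811 for Mir6386, 0.0528 to 0.0783 for Mir697).

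**Figure D2:**
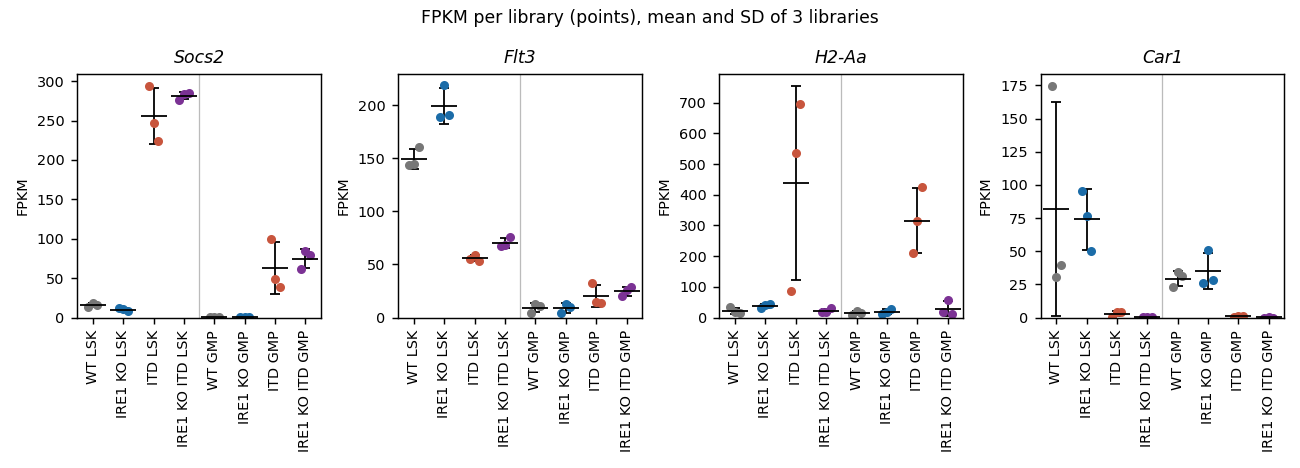
FPKM of Socs2, Flt3, H2-Aa and Car1 in each library (points), by genotype, for LSK on the left and GMP on the right of each panel; the black line is the mean and the bar the SD of 3 libraries. Socs2 was higher and Car1 lower in all ITD libraries than in WT, and H2-Aa was high in ITD but at 21.9 ± 7.03 FPKM in IRE1_KO_ITD LSK.

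In GMP, the same comparison asks what the duplication does in committed myeloid progenitors. Socs2 went from 0.626 ± 0.396 to 62.3 ± 32.9 FPKM (5.19 ± 0.34, limma adjusted p = 3.06e-05). The STAT5 target Cish rose by 2.70 ± 0.43 and Ifitm1 by 3.01 ± 0.29. The MHC class II genes H2-Ab1, H2-Eb1 and H2-Aa rose by 4.62 ± 0.45, 4.56 ± 0.52 and 4.42 ± 0.57, their invariant chain Cd74 by 4.29 ± 0.59, and the class I gene H2-Q8 by 3.77 ± 0.27 (limma adjusted p = 0.00216 or lower). Nov was listed at 0 in the 3 WT libraries and at 24.8, 13 and 10.8 FPKM in the ITD libraries. Ern1 passed narrowly (0.57 ± 0.16, limma adjusted p = 0.0440) and failed without WT replicate 3, WT replicate 2, ITD replicate 3 or ITD replicate 1 (adjusted p from 0.0926 to 0.169) and without the filter, with quantile normalization, a replicate block, the GC correction or sex, or in a fit of the 6 libraries alone (0.0685 to 0.205). Xbp1 (0.01 ± 0.18, limma adjusted p = 0.974), Flt3 (1.04 ± 0.45, 0.150) and Kit (-0.03 ± 0.14, 0.889) did not pass.

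Erythroid genes fell in ITD GMP, where 1 of 20 tested members rose and 13 fell (1 and 16 adjusted over the list alone) (camera adjusted p = 8.33e-17, 0.181 with an estimated correlation). Car1 fell (-4.07 ± 0.24), the erythroid factor Klf1 (-2.26 ± 0.11) and Cldn13 (-2.46 ± 0.16). B cell genes fell in part, where 9 of 17 tested members fell (15 adjusted over the list alone) (camera adjusted p = 1.11e-10, 0.417 with an estimated correlation). Cd79a stood at -3.79 ± 0.59, Ly6d at -3.59 ± 0.57 and the surrogate light chain gene Vpreb3 at -3.43 ± 0.53. Of the basophil and mast genes, 7 of 14 tested members fell (8 adjusted over the list alone) (camera adjusted p = 1.40e-07, 0.263 with an estimated correlation). They included Gzmb (-1.94 ± 0.26) and Ms4a2, the beta chain of the IgE receptor (-1.82 ± 0.36), which failed with sex as a covariate (adjusted p = 0.0718). Of the primary granule and GMP genes, 1 of 25 tested members rose and 14 fell (2 and 15 adjusted over the list alone) (camera adjusted p = 1.07e-08, 0.263 with an estimated correlation): the proteases Prtn3 and Elane fell (-0.94 ± 0.11 and -0.91 ± 0.15), Cst7 (-0.64 ± 0.09) and Nkg7 (-1.13 ± 0.18). With quantile normalization Prtn3 (-0.54) and Elane (-0.36) failed (adjusted p of 0.166 and 0.451), and Elane without the filter on low values (0.0547). The osteocalcin genes Bglap (-3.55 ± 0.84) and Bglap2 (-3.41 ± 0.77) fell, but not without WT replicate 3, WT replicate 2 or ITD replicate 1 (adjusted p from 0.0517 to 0.0848 and from 0.0650 to 0.0783), and Bglap not without ITD replicate 2; both failed with a pseudocount of 0.1 (0.0579 to 0.0679) and Bglap without the filter (0.0513). Late neutrophil genes had a median log2 fold change of -1.01 (camera adjusted p = 1.05e-04, 0.502 with an estimated correlation), with camera adjusted p = 0.255 without ITD replicate 1.

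Of the monocyte, macrophage and dendritic genes, 12 of 32 tested members rose (17 adjusted over the list alone, where 3 fell) (camera adjusted p = 1.05e-04, 0.494 with an estimated correlation). They included Irf8 (1.30 ± 0.13). Of the interferon response genes, 6 of 38 tested members rose (11 adjusted over the list alone). They included Tap1 (0.90 ± 0.11) and Psmb9 (0.49 ± 0.08), with no list call (camera adjusted p = 0.109). Cholesterol synthesis genes rose in part, where 9 of 25 tested members rose (9 adjusted over the list alone) (camera adjusted p = 0.00411, 0.494 with an estimated correlation). Srebf2 (0.95 ± 0.18) failed without WT replicate 3 (adjusted p = 0.0557) and Cyp51 (0.73 ± 0.15) without WT replicate 3 or 2 (adjusted p from 0.0627 to 0.0672). Of the STAT5 targets, 4 of 21 tested members rose (8 adjusted over the list alone, where 1 fell) (camera adjusted p = 0.0106, 0.494 with an estimated correlation), lost without WT replicate 1 (camera adjusted p = 0.0719). The XBP1 and ERAD secretory list lay lower, where 4 of 63 tested members fell (3 adjusted over the list alone) (camera adjusted p = 5.09e-05, 0.494 with an estimated correlation). They included Kdelr2 (-0.64 ± 0.11) and Pdia6 (-0.56 ± 0.13). Within the ER chaperones, 2 of 19 tested members fell (9 adjusted over the list alone) (camera adjusted p = 1.46e-05, 0.494 with an estimated correlation). Ppib stood at -0.38 ± 0.07. Pdia6 failed without WT replicate 3, WT replicate 2 or ITD replicate 3 (adjusted p from 0.0570 to 0.0924) and Ppib without WT replicate 3 (0.0589). With sex as a covariate Srebf2, Cyp51, Kdelr2, Pdia6 and Ppib failed (0.0559 to 0.129), Pdia6 also with quantile normalization (0.0572) and Ppib in a fit of the 6 libraries alone (0.0645).

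Limma called 1203 of 11249 genes in ITD against WT GMP, 829 higher and 374 lower, with 942 and 744 under a median-ratio size factor and 616 and 624 under quantile normalization. The count fell to 384 without WT replicate 3, 431 without WT replicate 2, 584 without ITD replicate 3 and 778 without ITD replicate 1, to 509 in a fit of the 6 libraries alone and to 271 with sex as a covariate. The short loci Mir7013 (72 bp), Mir1904 (80 bp) and Mir6994 (73 bp) were listed at 0 in all libraries of 1 group, and failed without WT replicate 3 (adjusted p of 0.0515, 0.0606 and 0.0582), Mir6994 also without WT replicate 2 (0.0536). Of genes tested in both populations, 239 rose with ITD in LSK and in GMP, where independent lists would share 127, and 87 fell in both, against 22.2.

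The ITD effect was tested for a difference between GMP and LSK, with all 24 libraries in 1 fit. Of the XBP1 and ERAD secretory genes, 28 of 63 tested members fell (34 adjusted over the list alone, where 1 rose) in this contrast (camera adjusted p = 9.33e-11, 0.302 with an estimated correlation), that is, their ITD effect was lower in GMP. P4hb differed by -0.78 ± 0.12 and Pdia5 by -1.72 ± 0.29. Of the ER chaperones, 12 of 19 tested members fell (14 adjusted over the list alone) (camera adjusted p = 9.33e-11, 0.165 with an estimated correlation). Hsp90b1 stood at -1.30 ± 0.19. The effect on S phase genes was lower in GMP as well, where 17 of 40 tested members fell (23 adjusted over the list alone) (camera adjusted p = 9.16e-08, 0.392 with an estimated correlation). Mcm10 stood at -1.17 ± 0.18 and Rrm1 at -0.75 ± 0.14. So was the effect on ribosome biogenesis genes, where 14 of 35 tested members fell (19 adjusted over the list alone) (camera adjusted p = 1.35e-08, 0.413 with an estimated correlation), with Ncl at -0.86 ± 0.18 and Ddx18 at -0.62 ± 0.13. Of the primary granule and GMP genes, 10 of 25 tested members fell (10 adjusted over the list alone) (camera adjusted p = 5.39e-07, 0.392 with an estimated correlation). Cst7 stood at -1.73 ± 0.25 and Nkg7 at -1.51 ± 0.25.

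Stem cell genes differed the other way, where 15 of 35 tested members rose (17 adjusted over the list alone, where 1 fell) (camera adjusted p = 4.67e-09, 0.144 with an estimated correlation). Ndn stood at 2.66 ± 0.29 and Fhl1 at 1.35 ± 0.25. Lymphoid priming genes did so too, where 6 of 22 tested members rose (6 adjusted over the list alone) (camera adjusted p = 0.00187, 0.413 with an estimated correlation), with Notch1 at 1.33 ± 0.22, Satb1 at 1.87 ± 0.33, Il12a at 1.44 ± 0.26 and Flt3 at 2.45 ± 0.48. Of single genes, Wfdc17 (3.75 ± 0.65) and Wfdc18 (3.02 ± 0.43) were among the highest, and Gzmb (-2.90 ± 0.40), Mcpt8 (-2.39 ± 0.44) and Prnp, the prion protein gene (-2.37 ± 0.37), were among the lowest. Limma called 1674 of 12348 genes, 797 with a higher and 877 with a lower effect in GMP, against 1243 and 736 with a median-ratio size factor. The count was 950 without WT GMP replicate 3, 927 without WT GMP replicate 2, 791 without WT LSK replicate 2 and 908 in a fit of the 12 libraries alone. The short loci Mir7023, Mir546, Mir6481, Mir6386 and Mir3535 passed, and each lost its call without 3 or more single libraries, ITD LSK replicate 2 among them (highest adjusted p 0.0815, 0.0668, 0.0739, 0.111 and 0.0922).

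GMP labelled IRE1_KO were compared with WT GMP to see which genes depend on IRE1α in myeloid progenitors. Secretory genes fell in part. Sec61b and Sec61g, subunits of the ER translocon, fell (-1.47 ± 0.10 and -1.5 ± 0.18), Sec24d (a coat protein of ER export vesicles) (-2.53 ± 0.30), Fkbp11 (an ER prolyl isomerase) (-2.72 ± 0.32), Pdia5 (-1.86 ± 0.20), P4hb (-1.15 ± 0.11), and Ostc (an oligosaccharyltransferase subunit) (-1.14 ± 0.10), with limma adjusted p = 0.00316 or lower. The calcium-binding Golgi protein gene Nucb2 fell by 1.53 ± 0.16 (limma adjusted p = 0.00143). P4hb, an abundant member, went from 606 ± 18.0 to 273 ± 11.6 FPKM. Sva, listed at 0 in the 3 WT libraries, was at 4.92, 6.56 and 5.58 FPKM in IRE1_KO, and Ern1 rose by 1.10 ± 0.16 (limma adjusted p = 1.03e-05 and 0.00958), while Xbp1 (0.35 ± 0.18, limma adjusted p = 0.455), Flt3 (-0.04 ± 0.45, 0.978) and Kit (0.28 ± 0.14, 0.440) did not pass.

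Among XBP1 and ERAD secretory genes, 23 of 63 tested members fell (45 adjusted over the list alone) (camera adjusted p = 4.04e-60, 0.0328 with an estimated correlation), and the signal peptidase subunit Spcs2 fell by 1.03 ± 0.09. Among ER chaperones, 5 of 19 tested members fell (12 adjusted over the list alone) (camera adjusted p = 3.37e-21, 0.0967 with an estimated correlation). Ppib stood at -0.81 ± 0.07, Dnajc3 at -0.79 ± 0.11 and Manf at -0.83 ± 0.12. Other genes of the ER stress response stayed short of the threshold: Dnajb9 (-0.77 ± 0.40, limma adjusted p = 0.466), the chaperone Hspa5 (-0.06 ± 0.18, 0.914), Edem1 (0.09 ± 0.26, 0.905), Herpud1 (-0.37 ± 0.09, 0.133), Ddit3 (-0.03 ± 0.29, 0.969) and Atf4 (-0.17 ± 0.19, 0.725). Bloc1s1, an mRNA that IRE1α can cleave, did not pass either (0.03 ± 0.11, limma adjusted p = 0.922). Cytosolic ribosomal protein genes had a median of -0.20 (camera adjusted p = 4.76e-22, 0.312 with an estimated correlation), of which Rpl10 fell (-0.60 ± 0.08), and oxidative phosphorylation genes had a median of -0.19 (camera adjusted p = 6.69e-14, 0.276 with an estimated correlation), a call lost with quantile normalization (camera adjusted p = 0.216). The primary granule list (-0.18, camera adjusted p = 0.00366) lost its call without IRE1_KO replicate 2 (0.266) and with quantile normalization, and had an adjusted p = 0.801 with an estimated correlation.

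Limma called 60 of 11249 genes in IRE1_KO against WT GMP, 3 higher and 57 lower. The count was 27 without WT replicate 3, 33 without WT replicate 2, 39 without WT replicate 1 and 33 without IRE1_KO replicate 3, and 95 with a median-ratio size factor and 39 with sex as a covariate. Ern1 and Dnajc3 failed without WT replicate 3 (adjusted p of 0.0611 for both), Ern1 also without WT replicate 2 (0.0518) or with a replicate block (0.0583), Dnajc3 without IRE1_KO replicate 3 (0.0512), and Manf without WT replicate 3, WT replicate 1 or IRE1_KO replicate 3 (adjusted p from 0.0554 to 0.0564).

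**Figure D3:**
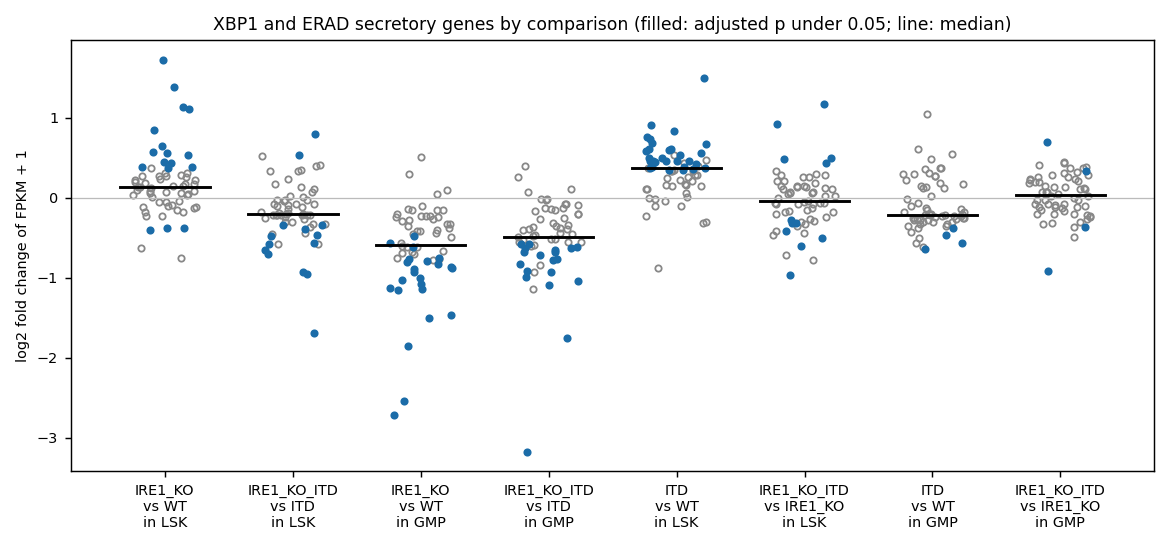
Log2 fold change of FPKM + 1 of each tested member of the XBP1 and ERAD secretory list in 8 comparisons (points; filled where the limma adjusted p lay under 0.05); the black line is the median. The medians were -0.57 and -0.50 for the Ern1 label in GMP, 0.14 and -0.21 in LSK, and 0.36 for ITD against WT in LSK.

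In LSK, the comparison of IRE1_KO with WT rests on the 3 libraries with the 1ng tag, so the label and whatever the tag marks cannot be separated within it. Xbp1 rose from 27.5 ± 8.07 to 48.5 ± 3.13 FPKM (0.83 ± 0.19, limma adjusted p = 0.00885) and Flt3 by 0.41 ± 0.09. Xbp1 failed with quantile normalization (0.57, adjusted p = 0.0528) and Flt3 with a median-ratio size factor (0.21, 0.0942) or the GC and length correction (0.15, 0.234). Ern1 rose by 0.69 ± 0.21 (limma adjusted p = 0.0350) but failed without any 1 of WT replicates 1 to 3 or IRE1_KO replicates 2 and 3 (adjusted p from 0.0566 to 0.114), with either scaling, the GC correction or sex, or without the filter (0.0701 to 0.176), and Kit did not pass (0.47 ± 0.16, limma adjusted p = 0.0546). Exosc6 (an exosome subunit) rose by 3.58 ± 0.22, Jund by 3.35 ± 0.62, the mRNA export factor Alyref by 3.33 ± 0.23, Zfp771 by 3.24 ± 0.27 and Taf10 by 3.20 ± 0.32 (limma adjusted p = 0.00224 or lower). Lars2, Gm12238 and the RNA component Rmrp fell (-3.82 ± 0.25, -3.77 ± 0.56 and -3.76 ± 0.38) (limma adjusted p = 4.90e-04 or lower).

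The secretory genes did not fall together in LSK. Of the XBP1 and ERAD secretory genes, 14 of 63 tested members rose and 3 fell (14 and 3 adjusted over the list alone), and the list did not stand apart from other genes (camera adjusted p = 0.988). Sec63, Txndc5 and Edem1 rose by 1.38 ± 0.13, 1.72 ± 0.19 and 1.13 ± 0.18, and Dnajc3 by 0.85 ± 0.12, whereas Sec61b fell by 0.38 ± 0.10, a call lost without WT replicate 1, IRE1_KO replicate 3 or IRE1_KO replicate 2 (adjusted p from 0.0677 to 0.0720) or in a fit of the 6 libraries alone (0.0971). Of the ER chaperones, 4 of 19 tested members rose (2 adjusted over the list alone) (camera adjusted p = 0.988). They included Hsp90b1 (0.39 ± 0.11), a call lost without WT replicate 2, IRE1_KO replicate 2 or IRE1_KO replicate 1 (adjusted p from 0.0703 to 0.0967), in a fit of the 6 libraries, with either scaling, the GC correction or sex (0.0543 to 0.246). Dnajb9 (-0.75 ± 0.33, limma adjusted p = 0.133), Hspa5 (0.27 ± 0.31, 0.596), Herpud1 (0.02 ± 0.14, 0.936), Ddit3 (-0.35 ± 0.21, 0.263), Atf4 (-0.61 ± 0.20, 0.0518) and Bloc1s1 (-0.04 ± 0.08, 0.781) did not pass.

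Cytosolic ribosomal protein genes lay lower in IRE1_KO LSK, where 16 of 76 tested members fell (20 adjusted over the list alone) (camera adjusted p = 9.85e-25, 0.994 with an estimated correlation). Rpl10 stood at -0.64 ± 0.12 and Rpl34 at -0.50 ± 0.11. No other list had a camera adjusted p under 0.05, but members rose in several. Of the S phase genes, 12 of 40 tested members rose and 1 fell (16 and 1 adjusted over the list alone) (camera adjusted p = 0.237). They included E2f1 (1.86 ± 0.19) and Chaf1a (1.74 ± 0.19). Of the ribosome biogenesis genes, 11 of 35 tested members rose (11 adjusted over the list alone) (camera adjusted p = 0.104). Noc2l stood at 2.13 ± 0.23 and Rrs1 at 2.30 ± 0.27.

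Limma called 2831 of 11955 genes in IRE1_KO against WT LSK, 2506 higher and 325 lower. The median of all genes moved by -0.17 with a median-ratio size factor and by -0.22 with quantile normalization, and the split became 1531 and 854 or 1408 and 1166. Of the short loci, Mir3960 (73 bp), Mir2861 (82 bp) and Mir1896 (81 bp, 4.11 ± 0.28) rose, and Mir877 (85 bp), Mir324 (89 bp), Mirlet7b (85 bp), Snord87 (87 bp) and Mir8097 (119 bp) fell. Mir3960 and Mir2861 were listed at 0 in all WT libraries and Mir877 and Mir324 in all IRE1_KO libraries. Mir877, Mirlet7b, Snord87 and Mir8097 lost their calls without IRE1_KO replicate 2 or 3, WT replicate 2 and in part other libraries (highest adjusted p 0.0801, 0.0929, 0.106 and 0.119), and Mir2861 without IRE1_KO replicate 2 (0.0590).

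GMP labelled IRE1_KO_ITD were compared with ITD GMP, which asks what the Ern1 label changes in the presence of the duplication. Some secretory genes fell: Sec24d from 14.6 ± 6.44 to 0.661 ± 0.310 FPKM (-3.17 ± 0.30, limma adjusted p = 0.00142). Sec61b (-1.09 ± 0.10), P4hb (-1.05 ± 0.11) and Serp1, a translocon stabiliser, (-0.82 ± 0.09) fell (limma adjusted p = 0.00235 or lower). P4hb and Serp1 failed in a fit of the 6 libraries alone (adjusted p from 0.0841 to 0.0910). Among XBP1 and ERAD secretory genes, 20 of 63 tested members fell (40 adjusted over the list alone, where 1 rose) (camera adjusted p = 2.44e-35, 0.160 with an estimated correlation). Among ER chaperones, 4 of 19 tested members fell (8 adjusted over the list alone, where 2 rose) (camera adjusted p = 6.51e-07, 0.707 with an estimated correlation). Ppib stood at -0.43 ± 0.07. The comparison shares no library with IRE1_KO against WT in GMP, and 28 genes fell in both, where independent lists would share 0.522. Sva rose by 2.59 ± 0.14 and Ern1 by 1.03 ± 0.16 (limma adjusted p = 1.82e-05 and 0.0134). Xbp1 (0.65 ± 0.18, limma adjusted p = 0.0958), Flt3 (0.37 ± 0.45, 0.689) and Kit (0.31 ± 0.14, 0.251) did not pass.

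MHC class II genes fell in IRE1_KO_ITD GMP. Cd74 went from 854 ± 285 FPKM in ITD to 74.4 ± 63.2 (-3.79 ± 0.59), and H2-Aa, H2-Eb1 and H2-Ab1 fell (-3.63 ± 0.57, -3.61 ± 0.52 and -3.30 ± 0.45) (limma adjusted p = 0.0140 or lower). Plbd1 fell (-2.71 ± 0.43), the dendritic cell factor Batf3 (-2.26 ± 0.33), and Irf7, a regulator of interferon genes, (-2.44 ± 0.46). Of the monocyte, macrophage and dendritic genes, 6 of 32 tested members fell (9 adjusted over the list alone, where 2 rose) (camera adjusted p = 2.59e-09, 0.707 with an estimated correlation). Of the interferon response genes, 3 of 38 tested members fell (19 adjusted over the list alone, where 1 rose) (camera adjusted p = 2.83e-15, 0.707 with an estimated correlation). Isg20 stood at -1.55 ± 0.24 and Bst2 at -0.83 ± 0.17. All of these genes, from Cd74 to Bst2, failed with sex as a covariate (adjusted p from 0.0640 to 0.176) and in a fit of the 6 libraries alone (0.0828 to 0.203), Plbd1, Irf7, Isg20 and Bst2 with a replicate block (0.0522 to 0.0733), Irf7 and Bst2 without the filter (0.0542 to 0.0673) and Batf3 with a pseudocount of 0.1 (0.0611). All failed without ITD replicate 3 (adjusted p from 0.0642 to 0.170), and H2-Aa, Cd74, Plbd1, Irf7 and Bst2 also without ITD replicate 2 or IRE1_KO_ITD replicate 1 (0.0555 to 0.146). Isg20 failed without ITD replicate 2 as well (0.0555), H2-Eb1 without IRE1_KO_ITD replicate 1 (0.0572), Irf7 and Bst2 without IRE1_KO_ITD replicate 3 (0.0767 and 0.0858) and Bst2 without IRE1_KO_ITD replicate 2 (0.0944). Late neutrophil genes had a median of -1.35 (camera adjusted p = 5.03e-06, 0.867 with an estimated correlation), a call lost without ITD replicate 2 (camera adjusted p = 0.105).

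Several genes rose in IRE1_KO_ITD GMP: the actin-severing protein gene Scin by 2.06 ± 0.30, the steroid enzyme gene Cyp11a1 by 2.04 ± 0.32, the aldo-keto reductase gene Akr1c12 by 1.79 ± 0.21, Stap2 by 1.77 ± 0.34, Ndrg2 by 1.43 ± 0.23 and Dmkn by 1.40 ± 0.19 (limma adjusted p = 0.0292 or lower). Apart from Akr1c12 these failed without ITD replicate 3 (adjusted p from 0.0642 to 0.132), and Scin, Cyp11a1, Stap2 and Ndrg2 also without ITD replicate 2 or IRE1_KO_ITD replicate 1, Stap2 and Ndrg2 without IRE1_KO_ITD replicate 3, and Stap2 without IRE1_KO_ITD replicate 2. All but Akr1c12 failed with sex as a covariate (0.0741 to 0.0943), all but Cyp11a1 in a fit of the 6 libraries alone (0.0610 to 0.181), Stap2 and Ndrg2 with a replicate block (0.0513 to 0.0558), and Stap2 with a pseudocount of 0.1 or without the filter (0.0575 to 0.0782). Of the fixed ER stress genes, Herpud1 fell by 0.45 ± 0.09 (limma adjusted p = 0.0301), whereas Dnajb9 (-0.84 ± 0.40, limma adjusted p = 0.298), Hspa5 (-0.06 ± 0.18, 0.880), Edem1 (-0.61 ± 0.26, 0.251), Ddit3 (-0.09 ± 0.29, 0.893), Atf4 (-0.23 ± 0.19, 0.543) and Bloc1s1 (0.27 ± 0.11, 0.226) did not pass. Ribosomal protein genes had a median of 0.18 (camera adjusted p = 6.36e-05, 0.867 with an estimated correlation). Herpud1 and Ppib failed without ITD replicate 3, IRE1_KO_ITD replicate 3 or IRE1_KO_ITD replicate 1 (adjusted p from 0.0592 to 0.155), Herpud1 also without IRE1_KO_ITD replicate 2 and Ppib without ITD replicate 2, and Ern1 without ITD replicate 3 (0.0563) or 2 (0.0555); all 3 failed with sex as a covariate, a replicate block or a fit of the 6 libraries (0.0505 to 0.227).

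Limma called 206 of 11249 genes in IRE1_KO_ITD against ITD GMP, 103 higher and 103 lower, with 80 and 161 under a median-ratio size factor. Without ITD replicate 1 the count was 759, without ITD replicate 3 it was 13, without ITD replicate 2 45, and without IRE1_KO_ITD replicates 3, 2 and 1 it was 101, 111 and 37. It was 12 in a fit of the 6 libraries alone, 15 with sex as a covariate and 130 with a pseudocount of 0.1. The short loci Mir760 (119 bp), listed at 0 in all ITD libraries, and Mir7013 (72 bp), listed at 0 in all IRE1_KO_ITD libraries, passed, and lost their calls without any 1 library of the pair but ITD replicate 1 (adjusted p from 0.0784 to 0.170 and 0.0767 to 0.136).

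In ITD LSK, MHC class II and many interferon genes fell with the Ern1 label. Cd74 went from 1120 ± 784 FPKM in ITD to 44.7 ± 15.3 in IRE1_KO_ITD (-4.25 ± 0.61), H2-Eb1 and H2-Aa fell (-4.73 ± 0.62 and -3.84 ± 0.64), and Plbd1 (-4.33 ± 0.54) (limma adjusted p = 0.00347 or lower). In WT LSK Cd74 stood at 108 ± 38.0 and H2-Aa at 21.6 ± 9.75 FPKM, against 21.9 ± 7.03 for H2-Aa in IRE1_KO_ITD. Of the monocyte, macrophage and dendritic genes, 23 of 33 tested members fell (24 adjusted over the list alone) (camera adjusted p = 2.79e-17, 0.556 with an estimated correlation). Ctss stood at -2.04 ± 0.26 and Mpeg1 at -2.93 ± 0.40. Of the interferon response genes, 34 of 45 tested members fell (37 adjusted over the list alone) (camera adjusted p = 7.54e-23, 0.556 with an estimated correlation). They included Ifi27l2a (-3.83 ± 0.57), the nucleic acid sensor Zbp1 (-2.38 ± 0.26) and Ifi44 (-2.62 ± 0.33). Late neutrophil genes fell in part, where 9 of 24 tested members fell (15 adjusted over the list alone, where 2 rose) (camera adjusted p = 2.03e-06, 0.577 with an estimated correlation), with Ifitm6 at -2.07 ± 0.41 and Itgam at -1.0 ± 0.23, the latter lost without ITD replicate 2 (adjusted p = 0.0513).

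Podxl, a sialomucin of the cell surface, rose from 7.70, 0.509 and 0.209 FPKM in the ITD libraries to 38.3 ± 4.40 in IRE1_KO_ITD (3.96 ± 0.56, limma adjusted p = 0.00198). Akr1c12 rose by 2.81 ± 0.51, the glycine-cleaving enzyme gene Gldc by 2.67 ± 0.56 and Fam20a by 2.59 ± 0.33 (limma adjusted p = 0.00868 or lower). Of the STAT5 targets, 7 of 22 tested members rose and 3 fell (10 and 3 adjusted over the list alone) (camera adjusted p = 0.0362, 0.577 with an estimated correlation). Gimap1 stood at 1.02 ± 0.11 and Socs1 at 1.43 ± 0.22. The call was lost without IRE1_KO_ITD replicate 3 (camera adjusted p = 0.0856). Xbp1 rose from 52.9 ± 10.7 to 147 ± 19.9 FPKM (1.47 ± 0.19, limma adjusted p = 0.00173). Ern1 (0.87 ± 0.21) and Flt3 (0.34 ± 0.09) rose, Ern1 not without IRE1_KO_ITD replicate 3 (adjusted p = 0.0623) and Flt3 not without that library (0.0849) or ITD replicate 3 (0.0735). Both failed with the GC correction (adjusted p of 0.0574 and 0.113, Flt3 at 0.20) and Ern1 with quantile normalization (0.0510), and Kit did not pass (0.07 ± 0.16, limma adjusted p = 0.814).

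Of the XBP1 and ERAD secretory genes, 2 of 63 tested members rose and 12 fell (5 and 14 adjusted over the list alone) (camera adjusted p = 9.91e-06, 0.556 with an estimated correlation). Sec61b fell (-0.95 ± 0.10), Sec61g (-0.93 ± 0.12) and P4hb (-0.48 ± 0.07), while Dnajc3 rose by 0.53 ± 0.12, a call lost without IRE1_KO_ITD replicate 3 (adjusted p = 0.0521), with quantile normalization (0.0521) or the GC correction (0.133). Of the ER chaperones, 1 of 19 tested members rose and 3 fell (1 and 4 adjusted over the list alone) (camera adjusted p = 0.00260, 0.577 with an estimated correlation), a call that quantile normalization ended. Bloc1s1 fell by 0.29 ± 0.08, not without ITD replicate 3, ITD replicate 2, IRE1_KO_ITD replicate 3 or IRE1_KO_ITD replicate 1 (adjusted p from 0.0676 to 0.0895) nor with sex, the GC correction or quantile normalization (0.0919 to 0.610). Dnajb9 (-0.58 ± 0.33, limma adjusted p = 0.244), Hspa5 (-0.43 ± 0.31, 0.356), Edem1 (0.51 ± 0.18, 0.0627), Herpud1 (-0.20 ± 0.14, 0.342), Ddit3 (-0.03 ± 0.21, 0.947) and Atf4 (-0.34 ± 0.20, 0.267) did not pass. Cytosolic ribosomal protein genes fell, where 61 of 76 tested members fell (73 adjusted over the list alone) (camera adjusted p = 4.56e-27, 0.556 with an estimated correlation). Rpl10 stood at -0.78 ± 0.12 and Rplp2 at -0.50 ± 0.09. Of the oxidative phosphorylation genes, 39 of 64 tested members fell (48 adjusted over the list alone) (camera adjusted p = 5.98e-18, 0.556 with an estimated correlation). Cycs stood at -0.67 ± 0.11 and Ndufa4 at -0.58 ± 0.10. Quantile normalization ended the calls of that list (camera adjusted p = 0.0503), of Rplp2 (-0.15, adjusted p = 0.189) and of Ndufa4 (-0.21, 0.207), the last lost with the GC correction too (0.0956).

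Limma called 2418 of 11955 genes in IRE1_KO_ITD against ITD LSK, 1586 higher and 832 lower, with 997 and 739 under quantile normalization, 1029 and 842 with the GC correction and 1356 and 1078 with a median-ratio size factor. The count was 1510 without ITD replicate 3, 1403 without ITD replicate 2, 1177 without IRE1_KO_ITD replicate 3 and 1529 without IRE1_KO_ITD replicate 1. This comparison shares no library with IRE1_KO against WT in LSK, and 1072 genes rose in both, where independent lists would share 332, and 36 fell in both, against 22.6. Of the short loci, Mir6942 (61 bp), Snord88a (90 bp), Mir7082 (92 bp) and Mir374 rose and were listed at 0 in all ITD libraries, and Snord73a (68 bp), Mir7050 (60 bp) and Snord34 (70 bp, -5.30 ± 1.70) fell, the former pair listed at 0 in all IRE1_KO_ITD libraries. Snord88a, Mir7082, Mir374 and Snord34 lost their calls without most single libraries of the pair, ITD replicates 2 and 3 and IRE1_KO_ITD replicates 1 and 2 among them (highest adjusted p 0.103, 0.0904, 0.0762 and 0.157).

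**Figure D4:**
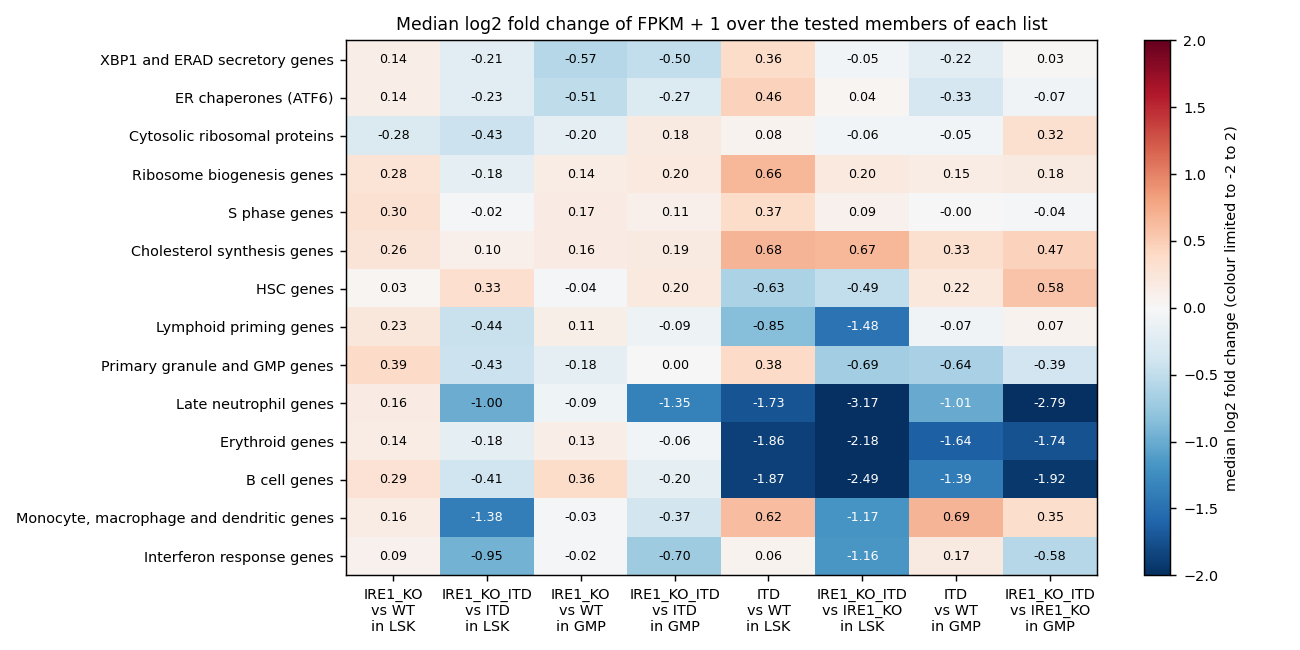
Median log2 fold change of FPKM + 1 over the tested members of 14 gene lists (vertical) in 8 comparisons (horizontal); colour gives the value from blue (lower in the first-named group) to red (higher) and is limited at -2 and 2. The interferon list was at -0.95 for IRE1_KO_ITD against ITD in LSK and 0.09 for IRE1_KO against WT.

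The difference between these effects of the Ern1 label, with and without ITD, was tested as an interaction. In LSK it includes the 3 libraries with the 1ng tag, so what the tag marks and the interaction cannot be separated. Cd74 differed by -5.01 ± 0.86, H2-Eb1 by -5.21 ± 0.88, Plbd1 by -4.92 ± 0.77 and Zbp1 by -2.46 ± 0.37 (limma adjusted p = 0.00979 or lower). Of the interferon response genes, 17 of 45 tested members fell (35 adjusted over the list alone) (camera adjusted p = 2.04e-12, 0.524 with an estimated correlation). Usp18 stood at -2.34 ± 0.38. Of the monocyte, macrophage and dendritic genes, 13 of 33 tested members fell (26 adjusted over the list alone) (camera adjusted p = 5.90e-09, 0.524 with an estimated correlation). Lgals3 stood at -2.83 ± 0.48. Podxl (3.82 ± 0.79), Gm12238 (3.77 ± 0.79), Lars2 (3.47 ± 0.35) and Mir6236 (3.34 ± 0.70) differed upward. Lars2, Gm12238 and Mir6236 were low in the 1ng libraries. Among XBP1 and ERAD secretory genes, 6 of 63 tested members fell (22 adjusted over the list alone) (camera adjusted p = 4.50e-05, 0.524 with an estimated correlation). Sec63 stood at -0.98 ± 0.19 and P4hb at -0.44 ± 0.10. Of the ribosome biogenesis genes, 4 of 35 tested members fell (22 adjusted over the list alone) (camera adjusted p = 3.93e-07, 0.524 with an estimated correlation), with Nop2 at -0.79 ± 0.16 and Wdr43 at -0.63 ± 0.14. Of the oxidative phosphorylation genes, 5 of 64 tested members fell (17 adjusted over the list alone) (camera adjusted p = 3.83e-08, 0.724 with an estimated correlation). Cycs stood at -0.88 ± 0.15 and Ndufa4 at -0.57 ± 0.15.

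Limma called 830 of 11955 genes for the interaction in LSK, 163 with a higher and 667 with a lower effect of the label in ITD. A median-ratio size factor, which moved the median of all genes by 0.13, gave 215 and 314, and quantile normalization, which moved it by 0.17, 232 and 353. With sex as a covariate the count was 82, and Cd74, H2-Eb1, Plbd1, Podxl, Usp18, Lgals3, Sec63, Cycs, Mir324, Gm12238, Mir6236, P4hb, Ndufa4, Nop2 and Wdr43 lost their calls (adjusted p from 0.0612 to 0.173). P4hb, Ndufa4 and Wdr43 also lost theirs under either scaling or the GC correction (0.0543 to 0.604), Nop2 and Mir6236 under quantile normalization (0.0683 to 0.316), Podxl and Gm12238 with a pseudocount of 0.1 (0.0544 to 0.0661), Mir6236 and Ndufa4 without the filter (0.0843 to 0.106) and P4hb with a replicate block (0.0504). The count was 526 without WT replicate 3, 413 without WT replicate 2, 354, 413 and 1549 without ITD replicates 3, 2 and 1, 412 without IRE1_KO replicate 2, and 343 and 416 without IRE1_KO_ITD replicates 2 and 1. Podxl failed without IRE1_KO_ITD replicate 2 (adjusted p = 0.0512), Nop2 without ITD replicate 3 (0.0526), Gm12238 and Mir6236 without WT, ITD or IRE1_KO_ITD replicate 2 among others (highest 0.0566 and 0.0524), and P4hb, Ndufa4 and Wdr43 without 6 or more single libraries, WT, ITD, IRE1_KO and IRE1_KO_ITD replicate 2 among them (highest 0.0838, 0.103 and 0.0778). The short loci Mir324, Snord73a and Mir7050 passed, each listed at 0 in every library of at least 1 group.

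In GMP, limma called 0 of 11249 genes for the interaction, with 1468 at an unadjusted p under 0.05. The 5 genes with the smallest p, none of which passed, were Slamf7 (-1.81 ± 0.25, limma adjusted p = 0.120), Snx22 (-1.77 ± 0.25), Tmem218 (0.97 ± 0.15), Amica1 (-1.48 ± 0.23) and the MHC class II activator Ciita (-1.91 ± 0.30, limma adjusted p = 0.140). Camera placed the interferon list lower (median -0.66) (camera adjusted p = 1.18e-06, 0.832 with an estimated correlation) and the monocyte, macrophage and dendritic list lower (-0.48) (camera adjusted p = 5.31e-04, 0.832 with an estimated correlation). It placed ribosomal protein (0.39) (camera adjusted p = 2.34e-20, 0.832 with an estimated correlation), oxidative phosphorylation (0.25) (camera adjusted p = 3.46e-08, 0.832 with an estimated correlation) and XBP1 and ERAD secretory genes (0.13) (camera adjusted p = 0.0113, 0.832 with an estimated correlation) higher. The monocyte call was lost without ITD replicate 2 (camera adjusted p = 0.0601) or IRE1_KO_ITD replicate 3 (0.360), and the XBP1 call without ITD replicate 2 (0.158), IRE1_KO replicate 3 (0.0610) or IRE1_KO_ITD replicate 3 (0.0540) or with quantile normalization (0.271). The oxidative phosphorylation call was lost with quantile normalization (0.0644) and the GC correction (0.0780). Without ITD replicate 1 the count of genes was 91, without IRE1_KO_ITD replicate 2 12, without IRE1_KO replicate 1 2, and 1 each without WT replicate 1, ITD replicate 3 and IRE1_KO replicate 2.

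The effect of ITD within the Ern1 label was taken from IRE1_KO_ITD against IRE1_KO. In LSK the second group is the 3 libraries with the 1ng tag. Socs2 went from 10.1 ± 2.08 to 282 ± 4.59 FPKM (4.69 ± 0.16), and Nov (5.61 ± 0.26), Podxl (4.93 ± 0.56) and Cish (3.28 ± 0.33) rose (limma adjusted p = 1.05e-04 or lower). Late neutrophil genes fell, where 1 of 24 tested members rose and 22 fell (1 and 22 adjusted over the list alone) (camera adjusted p = 3.90e-10, 0.537 with an estimated correlation). Mmp9 stood at -3.75 ± 0.31 and Mmp8 at -3.14 ± 0.29. Of the erythroid genes, 1 of 22 tested members rose and 19 fell (1 and 19 adjusted over the list alone) (camera adjusted p = 1.69e-08, 0.120 with an estimated correlation). Car1 stood at -6.04 ± 0.60, Rhd at -3.06 ± 0.29 and the globin genes Hba-a2 and Hba-a1 at -6.79 ± 2.01 and -5.85 ± 0.99. Of the B cell genes, 18 of 18 tested members fell (18 adjusted over the list alone) (camera adjusted p = 7.50e-12, 0.537 with an estimated correlation). Ms4a1 stood at -2.93 ± 0.22 and Faim3 at -2.53 ± 0.19. Interferon genes fell, where 1 of 45 tested members rose and 35 fell (1 and 36 adjusted over the list alone) (camera adjusted p = 3.39e-10, 0.650 with an estimated correlation). Rtp4 stood at -3.04 ± 0.27 and Xaf1 at -1.77 ± 0.18. Of the monocyte, macrophage and dendritic genes, 2 of 33 tested members rose and 16 fell (2 and 16 adjusted over the list alone) (camera adjusted p = 5.42e-04, 0.665 with an estimated correlation). Ms4a6b stood at -1.73 ± 0.27 and C1qb at -2.43 ± 0.38. The XBP1 and ERAD secretory list did not stand apart (camera adjusted p = 0.825): 5 of 63 tested members rose and 7 fell (5 and 5 adjusted over the list alone), Pdia5 at 1.17 ± 0.20 and Sec63 at -0.97 ± 0.13 among them.

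Limma called 3739 of 11955 genes in IRE1_KO_ITD against IRE1_KO LSK, 1399 higher and 2340 lower, with 2070 and 1824 under quantile normalization. With ITD against WT, which shares no library, 657 genes rose in both and 620 fell in both, where independent lists would share 208 and 170. The STAT5 list, where 7 of 22 tested members rose and 4 fell (7 and 4 adjusted over the list alone) (camera adjusted p = 0.0486, 0.654 with an estimated correlation), lost its call without IRE1_KO replicate 1 (0.218) or IRE1_KO_ITD replicate 3 (0.0900) and under both scalings. Hba-a2 failed without any 1 of the 3 IRE1_KO libraries, IRE1_KO_ITD replicate 3 or IRE1_KO_ITD replicate 1 (adjusted p from 0.0514 to 0.0889) and without the filter (0.0565). The short loci Mir6994 and Mir3058 rose from 0 in all IRE1_KO libraries, and Mir7050 and Snord73a were listed at 0 in all IRE1_KO_ITD libraries.

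In GMP, Socs2 went from 0.769 ± 0.483 to 74.7 ± 12 FPKM (5.44 ± 0.34), and Nov (5.10 ± 0.44), Ifitm1 (4.50 ± 0.29) and Cish (3.69 ± 0.43) rose (limma adjusted p = 6.48e-04 or lower). Of the erythroid genes, 16 of 20 tested members fell (18 adjusted over the list alone) (camera adjusted p = 2.39e-23, 0.0709 with an estimated correlation). Car1 stood at -5.09 ± 0.24, Klf1 at -2.30 ± 0.11 and Hba-a1 at -6.80 ± 1.39. Of the B cell genes, 16 of 17 tested members fell (17 adjusted over the list alone) (camera adjusted p = 1.07e-17, 0.280 with an estimated correlation). Cd79a stood at -4.88 ± 0.59 and Vpreb3 at -4.53 ± 0.53. Basophil and mast genes fell in part, where 1 of 14 tested members rose and 7 fell (1 and 7 adjusted over the list alone) (camera adjusted p = 2.11e-06, 0.280 with an estimated correlation). Ms4a2 stood at -2.77 ± 0.36 and Gzmb at -1.90 ± 0.26. The basophil protease gene Prss34 (-6.03 ± 1.17) and the eosinophil gene Prg2 (-5.35 ± 1.39) fell too. Of the late neutrophil genes, 7 of 24 tested members fell (17 adjusted over the list alone) (camera adjusted p = 1.17e-10, 0.541 with an estimated correlation). Ribosomal protein genes rose in part, where 16 of 76 tested members rose (48 adjusted over the list alone) (camera adjusted p = 1.72e-10, 0.543 with an estimated correlation). Rplp1 stood at 0.49 ± 0.09 and Rpl34 at 0.72 ± 0.13. The XBP1 and ERAD secretory list did not stand apart (camera adjusted p = 0.293). Kdelr2 stood at -0.92 ± 0.11 and Serp1 at 0.33 ± 0.09.

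Limma called 1459 of 11249 genes in IRE1_KO_ITD against IRE1_KO GMP, 953 higher and 506 lower, with 733 and 689 under a median-ratio size factor. The count was 743 without IRE1_KO replicate 3, 793 without IRE1_KO replicate 1, 708 without IRE1_KO_ITD replicate 2 and 837 without IRE1_KO_ITD replicate 1. With ITD against WT in GMP, which shares no library, 374 genes rose in both and 180 fell in both, where independent lists would share 70.2 and 16.8. Serp1, Prg2 and Snord88c failed without IRE1_KO replicate 3, IRE1_KO replicate 1 or IRE1_KO_ITD replicate 1 and without 2 more libraries each (adjusted p from 0.0681 to 0.131, 0.0651 to 0.0987 and 0.0548 to 0.0760). Serp1 also failed with a median-ratio size factor, the GC correction or a fit of the 6 libraries (0.0804 to 0.190), Prg2 with a replicate block, sex or no filter (0.0589 to 0.0661) and Snord88c without the filter (0.0523). The short loci Mir133c and Snord88c were listed at 0 in all IRE1_KO libraries.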

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

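The tests on genes changed at least 2-fold, on rises shared between the Ern1 comparisons, on genes that part the Ern1 labels and on the mean of the monocyte list in ITD LSK were chosen only after the result was seen, as were sex and the GC correction as alternatives.

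The effect of ITD differed between GMP and LSK in 1674 genes by a test of the difference. Of 100 drawn splits, the real one included, 3 gave as many genes. Splits also break up the ITD effect itself, so chance stays open for the difference. The highest other, 3129, swaps the ITD labels within 1 population and so tests the sum of effects. The effect of the Ern1 label differed with the Flt3 genotype in 830 genes in LSK, again a test of the difference. Of 100 drawn splits, 3 gave as many, but with the same limit, and the highest other drawn gave 1581. The split that swaps the Ern1 labels within 1 Flt3 genotype was not drawn; it gave 3723 genes and tests the sum of the effects. The interaction includes the 3 IRE1_KO libraries with the 1ng tag as 1 arm, so it and whatever the tag marks cannot be told apart. In GMP, limma called 0 genes for that interaction, with 1468 at an unadjusted p under 0.05, a count that the splits cannot test, since any split gives as many (100 of 100; the highest other drawn gave 9, and the swap 160).

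For the 3 against 3 comparisons the 10 splits of the libraries, of which 1 is the real one, are too few for a share under 0.05. Real count and highest other were 2650 and 3 for ITD against WT in LSK and 1203 and 2 in GMP; 2831 and 2 for IRE1_KO against WT in LSK and 60 and 2 in GMP; 2418 and 5 for IRE1_KO_ITD against ITD in LSK and 206 and 139 in GMP. For IRE1_KO_ITD against IRE1_KO they were 3739 and 1 in LSK and 1459 and 1 in GMP, and for GMP against LSK in WT 6212 and 1.

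The first pattern weighed was the 2831 genes called for IRE1_KO against WT in LSK, where 1 group is the 3 libraries with the 1ng tag. For changes of at least 2-fold, a GC and length trend as the whole cause was argued against by 894 of 908 that stayed called after the correction (median absolute log2 fold change 1.46 before and 1.27 after), and the FPKM scale by 848 of 858 rises that stayed with a median-ratio size factor. Rises shared with IRE1_KO_ITD against ITD numbered 1072, against 332 for independent lists. Both comparisons use 1 fit, whose spreads can raise overlap, so the 1ng batch stays open. For the smaller changes trend and scale stayed open, as 1822 of 2831 genes stayed after the correction and 1531 of 2506 rises with the size factor. The other 1434 rises had a median of 0.18 in IRE1_KO_ITD against ITD and 0.60 here. For them the batch and the Ern1 label cannot be told apart, as no other IRE1_KO LSK library exists.

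The second pattern was the lower MHC class II and interferon genes in IRE1_KO_ITD against ITD in LSK, where 57 of 78 tested members of the interferon and the monocyte, macrophage and dendritic lists fell. Sex as the whole cause was argued against by 47 of the 57 that stayed lower with sex as a covariate. Monocytes or dendritic cells carried over into the ITD libraries may explain it, although the LSK gate should remove them: the 29 list members that do not encode MHC class II proteins had a mean of -1.36 (SE over members 0.15), 19 of them called lower. Late neutrophil and B cell genes lay lower too (means -1.10, SE 0.20, and -0.62, SE 0.17). T and NK cell genes had -0.23 (SE 0.27). The first 2 lay lower in ITD than WT too (-1.63, -1.77), so such carry-over stays open. A change within LSK cells stays open as well, and ITD replicate 1 had far less of the signal than replicates 2 and 3 (H2-Aa at 85.3, 537 and 695 FPKM). A wrong Ern1 label on it stays open, as only 3 genes parted the other 23 libraries by label. All 3 put it with the unlabelled, Sva at 0 FPKM against 3.76 to 9.51 if labelled.

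The third pattern was the lower B cell, erythroid and late neutrophil genes in ITD LSK, where 48 of 64 tested members fell (means -1.77, -1.75 and -1.63). The monocyte, macrophage and dendritic list had a mean of 0.86 (SE over members 0.23), and 0.50 (SE 0.18) without MHC class II genes. Its call depended on single libraries, so fewer mature cells of every kind stays open. T and NK cell genes had 0.06 (SE 0.33). Other lists went with the fall: stromal and endothelial (-0.75, SE 0.27), megakaryocyte (-0.41, SE 0.14) and, within its spread, basophil and mast genes (-0.44, SE 0.29). Fewer cells of several kinds stays open, although the LSK gate should remove mature cells from all libraries. Sex as the whole cause was argued against by 36 of the 48 that stayed lower with sex as a covariate. Lower expression within LSK cells stays open too and was not tested.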

How the results depend on the processing

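Sex, the GC and length correction, leaving out the 1ng libraries and leaving out short loci were alternatives chosen only after the data were seen. Of the counts of called genes, 107 stayed within 1.5 times under the alternatives fixed beforehand and 53 did not; for the later ones the numbers were 33 and 6. IRE1_KO against WT in LSK, IRE1_KO_ITD against IRE1_KO in LSK and GMP against LSK in WT stayed within 1.5 times in all of them. With only the libraries compared, which leaves fewer samples to estimate the spread, the counts were 1689 for ITD against WT in LSK (2650 before), 509 in GMP (1203), 12 for IRE1_KO_ITD against ITD in GMP (206) and 908 for the difference of the ITD effect (1674). With sex as a covariate they were 1384 and 271 for ITD against WT in LSK and GMP, 82 for the interaction in LSK (830), 39 for IRE1_KO against WT in GMP (60) and 15 for IRE1_KO_ITD against ITD in GMP; all ITD libraries were female, so the covariate shares variation with the groups. A median-ratio size factor gave 529 for the interaction in LSK and 95 for IRE1_KO against WT in GMP, a replicate block 783 for ITD against WT, 35 for IRE1_KO against WT and 62 for IRE1_KO_ITD against ITD in GMP, the GC and length correction 98 for IRE1_KO against WT in GMP, a pseudocount of 0.1 130 for IRE1_KO_ITD against ITD in GMP, and no filter 3 for the interaction in GMP (0); the cause was not tested. Leaving out 1 library, counts ran from 1282 (without WT LSK replicate 2) to 2599 for ITD against WT in LSK, 384 (without WT GMP replicate 3) to 1609 in GMP, 27 (without WT GMP replicate 3) to 45 for IRE1_KO against WT in GMP, 1177 (without IRE1_KO_ITD LSK replicate 3) to 2342 for IRE1_KO_ITD against ITD in LSK, 13 (without ITD GMP replicate 3) to 759 (without ITD GMP replicate 1) in GMP, 708 (without IRE1_KO_ITD GMP replicate 2) to 1176 for IRE1_KO_ITD against IRE1_KO in GMP, 343 (without IRE1_KO_ITD LSK replicate 2) to 1549 (without ITD LSK replicate 1) for the interaction in LSK, 0 to 91 (without ITD GMP replicate 1) in GMP, and 791 (without WT LSK replicate 2) to 1849 for the difference of the ITD effect. Of 83 called list results followed through the alternatives that keep the preset correlation of camera, 68 kept their call and 15 lost it in at least 1. Camera with an estimated correlation ended the call of 77 of the 83, and fry that of 21, so most list calls depend on the preset correlation. The antioxidant list reversed under fry for IRE1_KO against WT in LSK. Its mean lay 0.0492 above that of other genes, yet camera placed it lower without a call. Depth limits genes near 1 FPKM, and relative depth varied only from 0.919 to 1.28.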

Other observations

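The average over both Flt3 genotypes, the test within ITD, sex as a covariate and the counts of genes that part the labels were chosen only after the results were seen. Averaged over WT and ITD backgrounds, the Ern1 label changed 160 genes in GMP by limma, 49 higher and 111 lower, and 34 members of the XBP1 and ERAD secretory list fell; with sex as a covariate, 95 genes were called and 29 members fell. A hypothesis stated before its test was that the label acts on this list differently in GMP and LSK. The difference of the IRE1_KO effects (GMP minus LSK) had a mean of -0.81 over 63 members, of which 39 were called lower, with camera adjusted p = 5.31e-33, adjusted p = 0.0181 with an estimated correlation and fry adjusted p = 4.40e-06. This rests on the 1ng libraries in LSK; in the ITD background, which uses none of them, the mean was -0.33, with camera adjusted p = 7.21e-07 and adjusted p = 0.547 with an estimated correlation, so it fell short there of the bar stated beforehand, which asked for both.

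A second hypothesis was that the rise of this list with ITD in LSK may need Ern1. Its mean was 0.32 (SE over members 0.04) for ITD against WT and -0.0415 (SE 0.0454) for IRE1_KO_ITD against IRE1_KO, as the hypothesis requires, but the latter again uses the 1ng libraries. The interaction, which tests the difference, called the list with camera adjusted p = 4.50e-05 and adjusted p = 0.524 with an estimated correlation.

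Of same-numbered LSK and GMP libraries, 10 of 12 pairs had the same sex by Xist and Y-linked genes and 2 did not. No gene but Sva, Scamp1 and Tmem39a parted all 12 libraries with the Ern1 label from the others, whereas 50 genes lay above and 60 below in all 12 with ITD.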
